A study of Mus musculus with 18 samples.

How the data were processed

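Mouse embryonic fibroblast lines were compared that carried a doxycycline-inducible dCas9, a Cas9 that no longer cuts DNA and that can carry another protein to a chosen sequence. Per the labels, the target was the major satellite repeat, the tandem array of a 234-bp unit that fills the pericentromeric heterochromatin of mouse chromosomes. The control line expressed dCas9 with no effector named, the repressor line dCas9-KM and the activator line dCas9-VPR. Per the labels, induction was 10 ng/ml doxycycline for 24 h in the control line, 100 ng/ml for 24 h in the repressor line and 10 ng/ml for 6 h in the activator line. Each line had 3 uninduced and 3 induced libraries, which made 6 groups and 18 libraries. The labels number the libraries of a group without saying whether they came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

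Per the labels, total RNA was extracted with TRI Reagent, treated with DNase, cleaned on columns and made into stranded, rRNA-depleted libraries that were read from both ends. The deposited table held whole-number read counts per gene for 47937 gene IDs, of which 18044 had no count in any library. The genome build was mm10 according to the submitters' processing notes. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here. Counts of overlapping genes, of genes on opposite strands and of near-identical copies are therefore uncertain. Gene symbols, transcript classes and 1-based GRCm38 coordinates were taken from GENCODE release M21, in which 47310 IDs were found, and the remaining 627 held 0.042% of the counts. The libraries held between 14928765 and 25262912 counts each.

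The table held genes only, so the lists of repeat families fixed before the data were examined, among them satellite repeats, IAP, L1, ERVK, B1 and B2 elements, were not analysed here. To follow the target, the spliced transcripts of the annotation were searched for 15-base words of the major satellite consensus. The 13 gene models with a transcript at least 50% covered were summed as 1 feature. This set was chosen from sequence, not from counts, but after the table had been opened. The models are near-identical copies, so reads may be placed on any of them and the sum is more certain than any member.

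Genes were tested with the edgeR quasi-likelihood test in its robust form after TMM normalization and filterByExpr, which left 16216 genes, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. All 18 libraries were fitted with 1 coefficient per group, which left 12 residual degrees of freedom, and the common biological coefficient of variation, the spread between libraries beyond counting error, was 0.0246. The 7 comparisons were induced against uninduced in each line, the difference between the activator or repressor line and the control line in that change (the interaction), and the uninduced activator or repressor line against the uninduced control line. These tests, the lists and most alternatives were chosen before the data were examined. Levels are counts scaled to a common library size (CPM), given as mean ± standard deviation of n = 3 libraries, and the standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. Where a group had no count, a floor of 3 counts over the group was used and the fold is given as "at least". Where it had 1 to 3 counts, the ratio has an exact 95% interval, and both cover counting error only. The edgeR intervals of the satellite sum use the 12 residual degrees of freedom. Groups of 3 were also compared by an exact two-sided permutation test, whose smallest possible p is 0.1.

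The 32 gene lists included immediate early genes, p53 targets, the integrated stress response driven by ATF4, interferon-stimulated genes, NF-kB targets, the unfolded protein response, heat shock, mitochondrially encoded genes, nuclear oxidative phosphorylation genes, G1/S and replication, G2/M, replication-dependent histones and cytosolic ribosomal proteins. They also held heterochromatin and silencing factors, centromere and kinetochore, Zfp zinc fingers, nuclear noncoding RNAs and germline genes silenced by DNA methylation. The rest were fibroblast matrix, contractile genes, cholesterol synthesis, glycolysis and hypoxia, pluripotency, 2-cell-stage genes, endogenous genes related to transgene parts, markers of 6 other cell types and the genes in the first assembled 10 Mb of a chromosome. The 29 lists with at least 3 tested members entered camera with a preset correlation of 0.01, and camera with an estimated correlation and fry were the alternatives. Camera tests a list against the other genes and fry tests it against no change, so their calls answer different questions. Members called were counted over all genes and again with p-values adjusted over the list alone.

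Genes are named by rules fixed beforehand. These took up to 8 called genes per direction with the largest fold and no overlap between the libraries of the groups, up to 3 called members per list by adjusted p, and up to 5 genes per direction for the uninduced lines. The text names a part of these, and some of the genes and list members tested are not reported here. Alternatives were RLE and upper-quartile normalization, TMM over nuclear genes, no filter, a filter of CPM 1 in 3 libraries, DESeq2, limma-voom, a replicate number block, a fit of the compared groups alone, adjusted p of 0.01, an absolute log2 fold change of at least 1 and each library left out in turn. Those chosen after seeing the data were total counts only, scaling to the 13 mitochondrially encoded protein genes, and TMM without Gm26917 and Gm42418, models with very high counts of which Gm26917 held 17.1% of the counts of the induced activator libraries. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

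In counts simulated from the fitted means and spread, the edgeR test recovered 66.7% of 1.5-fold, 84.6% of 2-fold and 96.8% of 4-fold changes in the activator induction, and between 61.9% and 98.5% over the other comparisons. The share of its calls that were false lay between 1.7% and 7.4%. The simulation gave all groups the same means apart from a small set of changed genes, raised and lowered in equal number. It therefore does not cover a change of most genes, as was called in the activator induction, or the choice of scaling there. A list raised by construction was called in 7 of 7 comparisons, and lists left unchanged in 0 of 14. Genes were drawn independently, so this does not test camera on lists whose members vary together. No libraries were duplicates, since the closest pair of a group differed by a chi-square of 1.33 per degree of freedom.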

Results

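RNA of mouse embryonic fibroblasts was compared in 18 libraries, 3 uninduced and 3 induced in each of a control line with dCas9 alone, a repressor line with dCas9-KM and an activator line with dCas9-VPR, all aimed at the major satellite repeat. Each library held between 14928765 and 25262912 counts. The first principal component held 78.4% of the variance of log2 CPM, and between 22641 and 23420 genes had a count in the induced activator libraries against 20107 to 21331 in the other libraries. A rise or fall below is a change past an adjusted p of 0.05 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over 16216 genes. Compared with the control line, induction was shorter in the activator line and used a higher doxycycline dose in the repressor line. The line with dCas9 alone was not induced for the shorter time or at the higher dose. A difference between lines in the change on induction therefore cannot be assigned to the effector rather than to time or dose. It also holds for these doses and times only. Gene lists called by camera were numerous in other splits of the libraries too, up to 9 against the real 10 in the activator and 8 against 8 in the control induction, so list calls are given as descriptions.

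The targeted repeat was followed through 13 satellite-bearing gene models, annotated transcripts made largely of major satellite sequence. In the activator line their summed level rose 129-fold on induction, from 31.5 ± 1.39 to 4036 ± 710 CPM (n = 3 libraries per group, log2 fold change 7.01, 95% interval 6.72 to 7.29, adjusted p = 2.89e-15). In the repressor line it fell from 5.95 ± 0.458 to 0.831 ± 0.078 CPM (log2 fold change −2.83, interval −4.07 to −1.59, adjusted p = 0.00622). In the control line it was 7.02 ± 1.05 CPM uninduced and 2.22 ± 0.646 CPM induced (log2 fold change −1.69, interval −2.59 to −0.80), a change that edgeR did not call (adjusted p = 0.115, unadjusted p = 0.00139). The uninduced activator line already held 4.39 times the satellite level of the uninduced control line (log2 fold change 2.13, adjusted p = 1.72e-05), and the uninduced repressor line was not shown to differ from it (log2 fold change −0.27, adjusted p = 0.837).

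**Figure D1:**
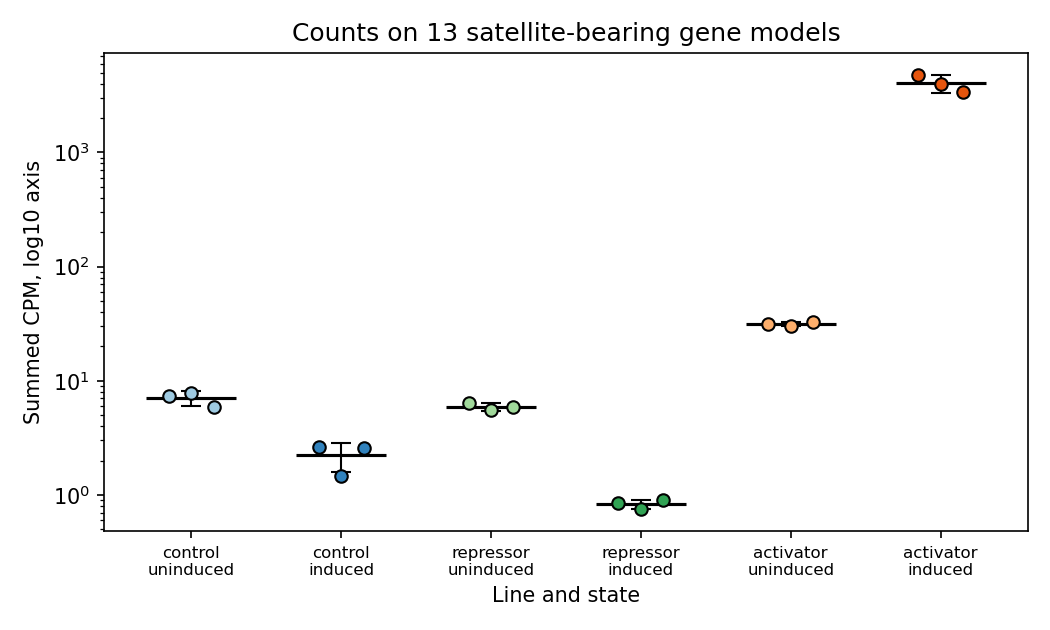
Summed level of the 13 satellite-bearing gene models in CPM on a log scale for each of the 6 groups. Points are libraries, lines are means and bars are standard deviations of n = 3, with means of 7.02, 2.22, 5.95, 0.831, 31.5 and 4036 CPM from the uninduced control to the induced activator group.

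The activator line's change in the satellite sum exceeded that of the control line by a log2 value of 8.70 (interval 7.68 to 9.72, adjusted p = 1.19e-09). The repressor line's change was not shown to differ from that of the control line (interaction log2 value −1.14, interval −2.88 to 0.61, adjusted p = 0.64), so these data do not credit the fall to the repressor domain. The exact two-sided permutation p was 0.1, the smallest possible, for each induction and for the uninduced activator line, and 0.3 for the uninduced repressor line. Each of the 13 models rose in the activator induction, among them Gm26870 (ENSMUSG00000097312.1, chromosome 9, 3000282 to 3038313) and Gm10800 (ENSMUSG00000075014.1, chromosome 2, 98666547 to 98667301). Only Gm10800 fell in the repressor induction, from 3.63 ± 0.468 to 0.338 ± 0.0969 CPM (log2 fold change −3.38, SE 0.80, adjusted p = 0.0167). The repressor fall was lost with limma-voom (adjusted p = 0.285 for the sum and 0.306 for Gm10800), and Gm10800 was lost without induced repressor library 1, 2 or 3 (adjusted p = 0.0577, 0.0543 and 0.0631). Other tools and settings gave other calls, for a reason not tested. With edgeR the control fall was called when scaled to mitochondrially encoded genes (adjusted p = 8.44e-25), in a fit of its groups alone and with a replicate block across lines. DESeq2 called the control fall (adjusted p = 8.05e-13) and the interaction of the repressor line (adjusted p = 0.0331). Over the alternatives these adjusted p lay between 8.44e-25 and 0.535 and between 0.00457 and 0.891.

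Induction of the activator changed most of the transcriptome within 6 h. Hyaluronan synthase Has2 (ENSMUSG00000022367.7, chromosome 15, 56665627 to 56694539), which makes a major matrix polysaccharide, fell 7.2-fold from 48.9 ± 1.18 to 6.79 ± 0.974 CPM (n = 3 per group, log2 fold change −2.85, SE 0.07, adjusted p = 8.11e-53). The macrophage growth factor Csf1 (ENSMUSG00000014599.10, chromosome 3, 107741048 to 107760469) fell 3.93-fold from 569 ± 2.66 to 145 ± 11.3 CPM (log2 fold change −1.97, SE 0.03, adjusted p = 5.59e-55). The kinase gene Plk2 fell from 224 ± 2.93 to 60.6 ± 1.2 CPM (log2 fold change −1.89, adjusted p = 3.03e-63). The early response transcription factor Egr1 (ENSMUSG00000038418.7, chromosome 18, 34859823 to 34864984) rose from 91.3 ± 2.63 to 302 ± 12.2 CPM (log2 fold change 1.73, SE 0.03, adjusted p = 6.95e-62). The test called 6190 genes higher and 6028 lower, 75.3% of those tested, of which 1554 and 1928 changed at least 2-fold, and the unadjusted count was 12453. The libraries of the groups did not overlap in 12372 genes, 76.3% against 10% by chance.

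The balance of that response depended on how the libraries were scaled. With TMM 50.7% of the called genes were higher, with total counts only 32.8% and with scaling to mitochondrially encoded genes 9.8%. These scalings shifted the median log2 change of all genes from 0.004 to −0.219 and −0.735, and upper-quartile normalization shifted it to 0.108. Has2, Csf1, Plk2 and Egr1 kept their direction and call in every alternative.

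Many genes without measurable RNA became expressed in the activator line. Keg1 (ENSMUSG00000024694.9, chromosome 19, 12695786 to 12719902) had no count before induction and reached 7.22 ± 0.521 CPM, at least 159-fold higher (adjusted p = 6.35e-32). Its neighbour Glyat (ENSMUSG00000063683.12, chromosome 19, 12633308 to 12653911), a mitochondrial glycine acyltransferase of liver and kidney, had 1 count before and 846 after (ratio 1070, 95% interval 192 to 42300, adjusted p = 1.06e-44). The unconventional myosin Myo3b (chromosome 2, 70039126 to 70429198) showed a ratio of 673 (interval 120 to 26600, adjusted p = 1.08e-14). A rise of at least 8-fold was found for 852 genes and a fall of that size for 14, and 819 of the 852 lay under 1 CPM before induction. Of the genes called higher, 170 had no count in the uninduced activator libraries, and the 8-fold count stayed at 852 with these set to their bound.

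**Figure D2:**
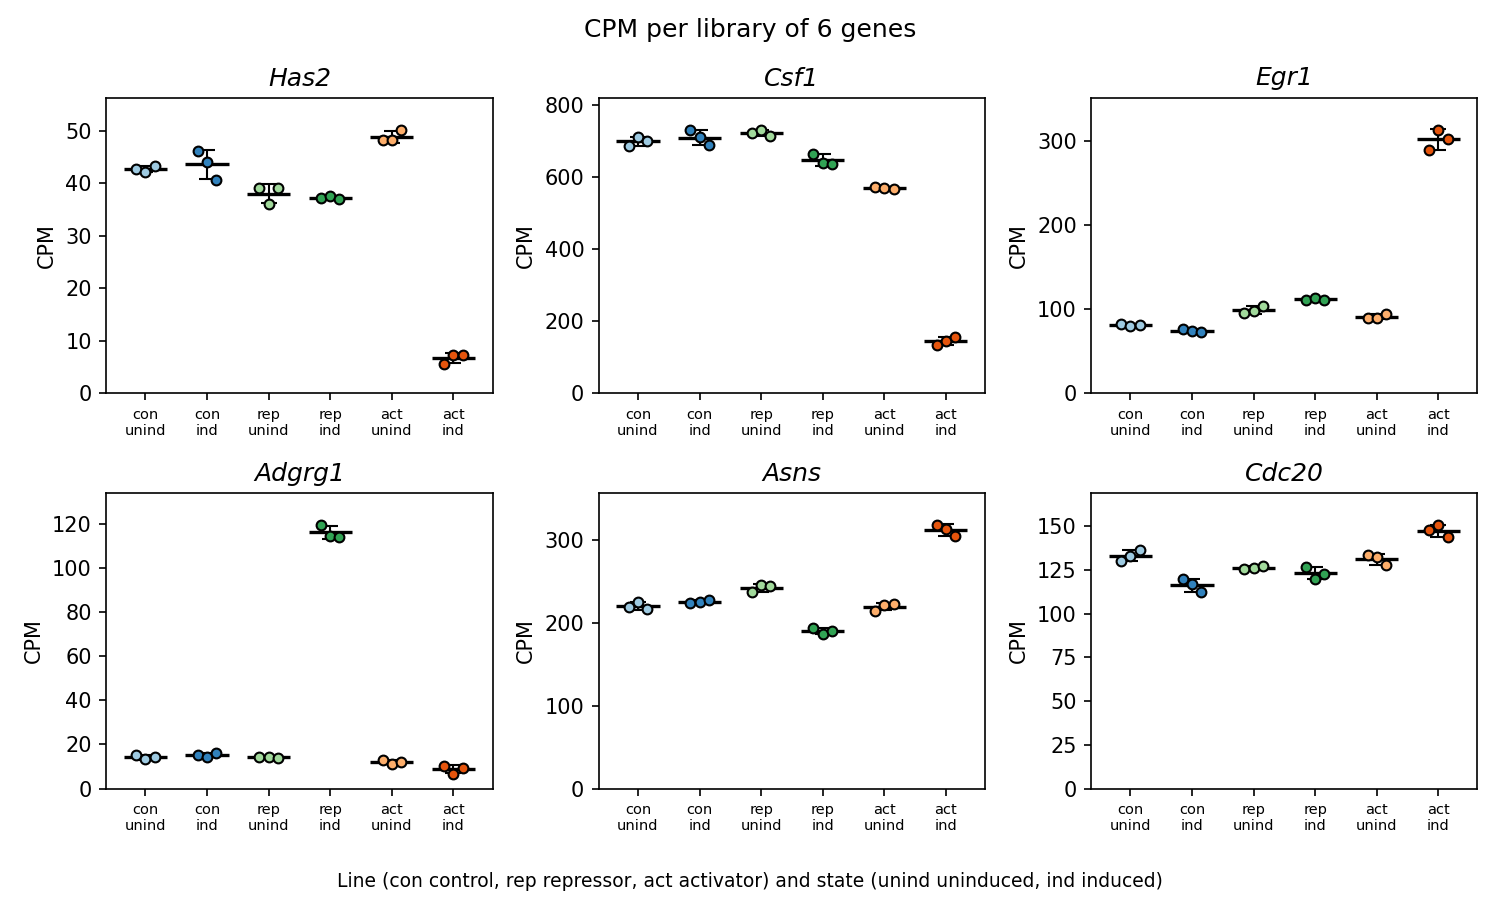
Level in CPM of Has2, Csf1, Egr1, Adgrg1, Asns and Cdc20 in each of the 6 groups. Points are libraries, lines are means and bars are standard deviations of n = 3, with Has2 at 6.79 against 48.9 CPM in the activator line, Adgrg1 at 116 against 14.1 CPM in the repressor line and Cdc20 at 116 against 133 CPM in the control line, induced against uninduced.

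Genes of translation and respiration rose as groups in the activator line. Of 81 cytosolic ribosomal protein genes 80 rose and none fell, 1 being not called, with Rplp0, the stalk protein of the large subunit, at 2190 ± 95.6 against 1460 ± 20.2 CPM (list median log2 fold change 0.55, camera adjusted p = 5.77e-17). All 33 nuclear oxidative phosphorylation genes rose (median 0.53, adjusted p = 2.5e-09), among them the ATP synthase subunit Atp5b at 1740 ± 67.5 against 1150 ± 19.5 CPM. All 15 mitochondrially encoded genes rose (median 0.745, adjusted p = 0.000653), among them mt-Co1 at 5010 ± 244 against 2870 ± 80.9 CPM and mt-Cytb at 1740 against 981 CPM. Scaled to mitochondrially encoded genes, the medians turned to −0.186 for ribosomal and −0.21 for oxidative phosphorylation genes, and Rplp0 and Atp5b turned to log2 values of −0.15 and −0.14, while mt-Co1 and mt-Cytb, members of the scaling set, lost their calls (adjusted p = 0.184 and 0.0707). All 3 calls were lost with an estimated correlation (adjusted p = 0.301 for ribosomal and mitochondrially encoded genes and 0.211 for oxidative phosphorylation genes).

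Replication, division, protein folding and matrix genes also shifted upward in the activator line under TMM. The replication helicase gene Mcm4 rose from 215 ± 3.81 to 340 ± 9.95 CPM, and of 38 G1/S genes 27 rose, 7 fell and 4 were not called (8 lower when adjusted over the list alone, median 0.353, adjusted p = 0.000733). Of 36 G2/M genes 24 rose and 9 fell, cyclin Ccnb2 rising (log2 fold change 0.68) and the phosphatase gene Cdc25b falling (−0.96), with median 0.206 and adjusted p = 0.0239. The chaperone gene Pdia3 rose from 482 ± 5.8 to 708 ± 9.16 CPM with 16 of 20 unfolded protein response genes while 3 fell, Xbp1 among them (−0.92), with median 0.38 and adjusted p = 0.00477. Fibroblast matrix genes divided into 18 higher and 6 lower of 26, Sparc rising (0.46) and Pdgfra falling (−1.14), with median 0.234 and adjusted p = 0.0458. That call was lost without uninduced activator library 1, 2 or 3 or induced activator library 3 (adjusted p = 0.0766, 0.0658, 0.0509 and 0.0722), and with a replicate block within each line (0.0531). Scaled to mitochondrially encoded genes the medians of these 4 lists turned to −0.385, −0.533, −0.36 and −0.504 in the order given, and Mcm4, Ccnb2, Pdia3 and Sparc turned negative as well. With total counts only the G2/M median turned to −0.018 (14 higher and 16 lower) and that of matrix genes was 0.009 (8 and 8), so neither shifted upward there, and those of G1/S and unfolded protein response genes were 0.129 and 0.157. The 4 calls were lost with an estimated correlation (adjusted p = 0.312 for matrix genes and 0.301 for the rest).

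Lists that fell in the activator line kept that direction under every scaling. NF-kB target genes divided into 7 higher and 14 lower of 24 (median −0.637, adjusted p = 0.0374), with Tnfaip3, a brake on NF-kB signalling, at 12.3 ± 0.0863 against 52.9 ± 2.43 CPM and the adhesion molecule Vcam1 also lower (log2 fold change −0.77). Of 359 Zfp zinc finger genes 214 fell and 68 rose (median −0.366, adjusted p = 0.000131), Zfp609 (−1.32) and Zfp462 (−1.43) falling while Zfp385b rose from 6 counts to 19.3 ± 0.828 CPM. Nuclear noncoding RNAs fell in 14 and rose in 4 of 19 (median −0.623, adjusted p = 0.014), among them the snoRNA host gene Gas5 at 47.6 ± 3.93 against 120 ± 2.53 CPM, Snhg5 (−1.54) and the imprinted Kcnq1ot1 (−0.86). These calls too were lost with an estimated correlation (adjusted p = 0.301), under which none of the 10 lists called here held. Fry called 25 lists, but it tests a list against no change and not against other genes, so with most genes called it does not bear on these calls.

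**Figure D3:**
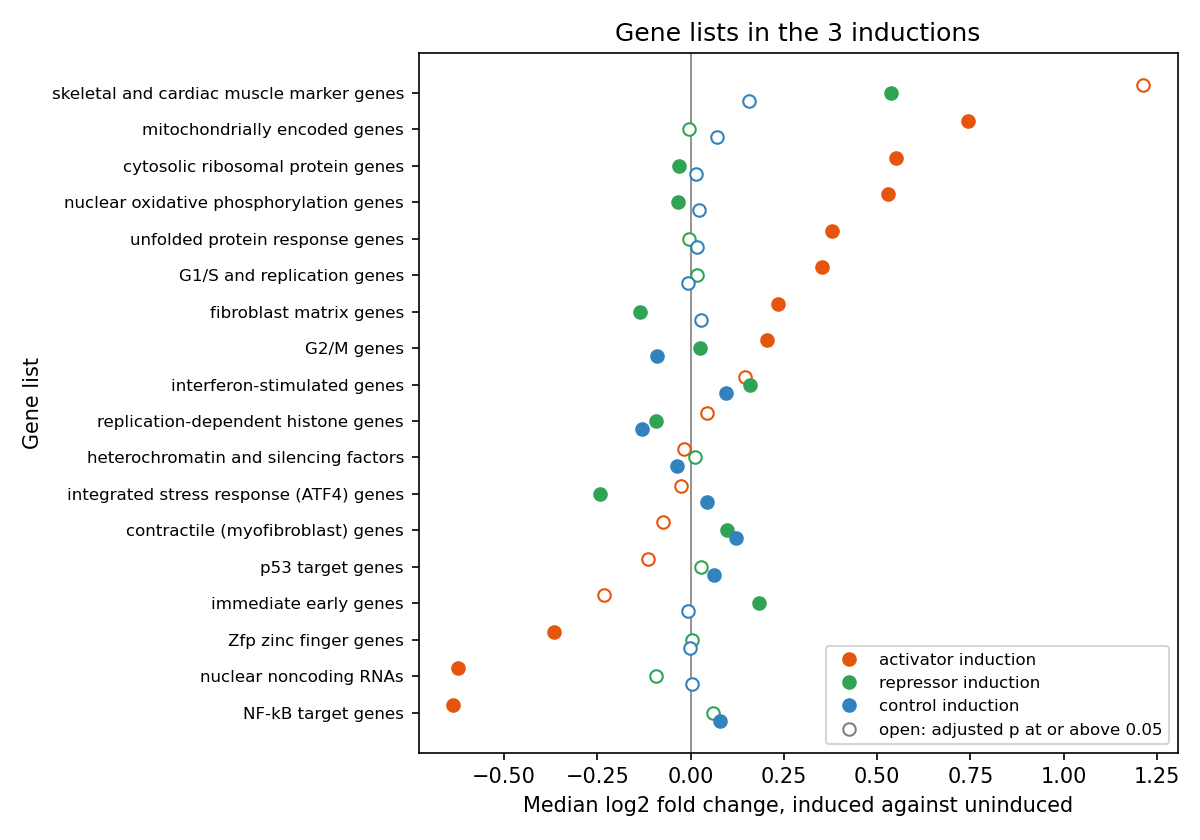
Median log2 fold change of tested members on the horizontal axis for 18 gene lists in the 3 inductions, filled points having a camera adjusted p under 0.05 and open points not. Medians ran from −0.637 for NF-kB targets to 0.745 for mitochondrially encoded genes among the filled activator points, and with scaling to mitochondrially encoded genes those of ribosomal (−0.186), oxidative phosphorylation (−0.21), G1/S (−0.385), G2/M (−0.533), unfolded protein response (−0.36) and matrix genes (−0.504) turned negative, as did the stress response in the control line (−0.016).

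The other 19 lists were not called in the activator line, the lowest adjusted p being 0.16, although single members moved strongly. Immediate early genes showed 8 higher and 13 lower of 27, with Egr1 higher and the phosphatase gene Dusp6 (−1.94) and Klf6 (−1.4) lower. The p53 targets showed 10 and 12 of 25, integrated stress response genes 8 and 9 of 23 and interferon-stimulated genes 5 and 4 of 19. The counts were 11 and 4 of 19 for heat shock genes and 19 and 10 of 37 for centromere and kinetochore genes. Heterochromatin and silencing factors showed 15 higher and 18 lower of 44 (14 higher when adjusted over the list alone). The lower ones included the histone methyltransferase gene Setdb1 at 57.5 against 106 CPM (log2 fold change −0.88, SE 0.04, adjusted p = 6.75e-36) and the DNA methyltransferase gene Dnmt3b at 3.81 ± 0.647 against 10.9 ± 0.517 CPM (−1.50, SE 0.11). Histone genes showed 19 higher and 13 lower of 64 (15 and 12 over the list alone) and contractile genes 7 and 6 of 14 with Ankrd1 (−1.70) lower. Cholesterol synthesis genes showed 13 and 7 of 23, and genes in the first assembled 10 Mb of a chromosome 491 and 401 of 1170. Glycolysis and hypoxia genes showed 15 and 8 of 28, with Vegfa (−1.48) and Hk2 (−1.17) lower and a median of 0.279 against a mean of −0.025.

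Induction of the repressor changed fewer genes. The adhesion receptor gene Adgrg1 (ENSMUSG00000031785.15, chromosome 8, 94974751 to 95014217) rose 8.23-fold from 14.1 ± 0.0912 to 116 ± 2.93 CPM (n = 3 per group, log2 fold change 3.04, SE 0.06, adjusted p = 1.25e-57). The related receptor gene Adgrf5 rose from 1.02 to 3.04 CPM (log2 fold change 1.58, SE 0.22, adjusted p = 3.84e-08), the arginine deiminase gene Padi3 from 1.86 to 5.17 CPM (1.48, SE 0.17) and the glutathione transferase gene Gstm5 from 8.19 to 22.1 CPM (1.44, SE 0.09). Sytl2, a vesicle transport gene, fell from 7.69 to 2.97 CPM (−1.38). Its uninduced level was raised in this line, as the uninduced control libraries held 2.047 to 2.755 CPM. The test called 845 genes higher and 745 lower, 9.8% of those tested, of which 50 and 23 changed at least 2-fold, with 3411 genes at an unadjusted p below 0.05. The libraries of the groups did not overlap in 4328 genes, 26.7% against 10% by chance. With total counts only 73.4% of the called genes were higher against 53.1% with TMM, and without induced repressor library 2 the genes lower numbered 484.

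Integrated stress response and fibroblast matrix genes shifted downward in the repressor line, and interferon-stimulated genes upward. Of 23 integrated stress response genes 17 fell and none rose (19 and 1 when adjusted over the list alone), including asparagine synthetase Asns (ENSMUSG00000029752.12) at 190 ± 3.57 against 243 ± 4.77 CPM (log2 fold change −0.35, SE 0.03, adjusted p = 3.54e-17), Trib3 (−0.54) and Atf5 (−0.37). The list median was −0.243 and the camera adjusted p = 2.4e-19. Before induction 10 of these 23 genes were higher in the repressor line than in the control line and 0 lower. The fall of the list thus started in part from a raised level. Of 26 fibroblast matrix genes 16 fell and 2 rose (17 and 3 over the list alone), with collagen Col1a2 at 3350 ± 17.2 against 4320 ± 63.1 CPM, Col1a1 (−0.25) and the crosslinking oxidase gene Lox (−0.38) lower (median −0.137, adjusted p = 3.7e-08). Interferon-stimulated genes rose in 4 of 19 with none lower, Ddx58 (0.35) and Xaf1 (0.5) among them (median 0.16, adjusted p = 0.00273). These 3 lists held with an estimated correlation (adjusted p = 0.00139, 0.027 and 0.027). The interferon list had the same mean log2 fold change, 0.207, in the repressor and control inductions. Its interaction was not called (camera adjusted p = 0.603), so its rise was not shown to differ from that with dCas9 alone.

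The remaining 7 lists called in the repressor induction did not hold with an estimated correlation. Contractile genes rose in 8 of 14 with none lower, with Ankrd1, a strain-responsive nuclear protein, at 74.5 ± 1.3 against 37.7 ± 0.567 CPM, Ccn2 at 224 ± 7.97 against 125 ± 2.3 CPM and Tagln (0.33) higher (median 0.098, adjusted p = 1.83e-06, and 0.0512 with an estimated correlation). This list also rose in the control induction (median 0.121), and its interaction was not called (camera adjusted p = 0.112). Immediate early genes rose in 9 of 27 with none lower (11 over the list alone), among them Ccn1 (0.30) and Dusp6 (0.36), with median 0.183 and adjusted p = 1.03e-06, and 0.0512 with an estimated correlation. Muscle markers rose in 2 of 8, Des (1.10) and Tnnt2 (0.70), with 1 lower over the list alone (adjusted p = 0.0209, 0.108 with an estimated correlation and 0.059 without uninduced library 3). Histone genes fell in 8 of 64 (9 over the list alone), among them Hist2h4 (−0.21) and Hist1h3d (−0.25), with adjusted p = 5.35e-05, and 0.662 with an estimated correlation. G2/M genes rose in 5 of 36 (7 over the list alone, Dlgap5 with 0.25 among them, adjusted p = 0.0228, 0.433 with an estimated correlation and 0.13 without induced library 2). Ribosomal protein genes fell in 4 of 81 (2 over the list alone) with Rplp0 (−0.13) lower, and oxidative phosphorylation genes in 3 of 33 (1 higher and 5 lower over the list alone) with Uqcrc2 (−0.14) lower. Rplp0 and Uqcrc2 lost their calls with scaling to mitochondrially encoded genes (adjusted p = 0.0801 and 0.128). The adjusted p of these lists were 0.0126 and 0.0209, 0.878 and 0.662 with an estimated correlation, 0.676 and 0.216 without induced library 1, and 0.274 for ribosomal genes without uninduced library 1. No call was made for the other 19 lists, the lowest adjusted p being 0.0505. Among their members the silencing cofactor gene Atf7ip rose from 81.5 ± 3.01 to 121 ± 1.89 CPM (0.58, SE 0.03, adjusted p = 1.35e-24). The methyl-CpG reader gene Mbd1 rose (0.40) and the heat shock gene Hspa1b rose from 2.38 to 5.49 CPM (1.2, SE 0.15).

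Induction of dCas9 alone changed few genes, and by little. Rpl7l1 (ENSMUSG00000063888.6, chromosome 17, 46773907 to 46782672), a ribosomal protein paralogue, rose from 125 ± 4.85 to 162 ± 5.31 CPM (n = 3 per group, log2 fold change 0.37, SE 0.03, adjusted p = 6.49e-15). The anaphase activator gene Cdc20 (ENSMUSG00000006398.15, chromosome 4, 118432901 to 118437352) fell from 133 ± 3.06 to 116 ± 3.7 CPM (−0.19, adjusted p = 8.75e-05), and the spindle checkpoint kinase gene Bub1b from 181 to 158 CPM (−0.20). The nuclear noncoding RNA Neat1 fell from 868 to 773 CPM (−0.17, adjusted p = 5.53e-05). The test called 41 genes higher and 34 lower, with 0 and 2 of them at 2-fold and 1741 genes at an unadjusted p below 0.05. The libraries of the groups did not overlap in 2512 genes, 15.5% against 10% by chance.

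The control counts depended on single libraries and on scaling. Genes higher numbered 14, 26 and 12 without uninduced library 1, 2 or 3 and 14 and 17 without induced library 2 or 3. Genes lower numbered 21 without uninduced library 1 and 22 and 20 without induced library 2 or 3. Of the called genes 54.7% were higher with TMM, 78.4% with total counts only, 5.8% with scaling to mitochondrially encoded genes and 34.2% with DESeq2, and 40%, 31.6% and 38.9% without uninduced library 1 or 3 or induced library 2.

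Division genes shifted downward and contractile genes upward in the control line. Of 36 G2/M genes 7 fell and none rose (22 and 1 over the list alone), with Cdc20, Hmmr (−0.18) and Prc1 (−0.15) lower (median −0.091, camera adjusted p = 2.08e-16). Heterochromatin and silencing factors fell in 1 of 44 (3 over the list alone, adjusted p = 0.000377). Contractile genes rose in 2 of 14 (10 over the list alone, median 0.121, adjusted p = 5.63e-09), with Thbs1 (ENSMUSG00000040152.8) at 1700 ± 20.9 against 1540 ± 36.6 CPM and Ccn1 at 252 against 225 CPM. The call of Ccn1 was lost without uninduced library 1 (adjusted p = 0.0956), and those of Thbs1 and Ccn1 with scaling to mitochondrially encoded genes (0.486 and 0.428). Interferon-stimulated genes had no member called by edgeR over all genes (5 higher over the list alone, adjusted p = 0.00113), and p53 targets rose in 1 of 25 (3 over the list alone, adjusted p = 0.0027, 0.0727 without uninduced library 3). These 5 lists held with an estimated correlation (adjusted p = 0.00288, 0.0128, 0.0162, 0.0156 and 0.0466), and the genes in the first assembled 10 Mb of a chromosome, with 5 lower of 1170, were called with it but not with the preset (adjusted p = 0.0162 and 0.501). Against no change, and not against other genes, fry gave that list an adjusted p of 0.00541. No contractile gene and 5 G2/M genes were called with scaling to mitochondrially encoded genes, and with total counts only 7 contractile and 6 G2/M genes.

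The other lists called in the control line were lost with an estimated correlation. Histone genes fell in 3 of 64 (13 over the list alone), with Hist2h4 at 132 against 155 CPM and Hist1h1b at 212 against 242 CPM (adjusted p = 3.19e-13, and 0.237 with an estimated correlation). NF-kB targets and integrated stress response genes were called upward with no member called over all genes (0 and 3 higher over the list alone, adjusted p = 0.0122 and 0.0188, and 0.237 and 0.292 with an estimated correlation). The NF-kB call was lost without uninduced library 1 (adjusted p = 0.11) or induced library 1 (0.187), and the stress call without uninduced library 3 (0.136) or induced library 2 (0.0882). The stress list median of 0.044 turned to −0.016 with scaling to mitochondrially encoded genes. The remaining 21 lists were not called, the lowest adjusted p being 0.11.

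The activator line's response to induction differed from that of the control line at 63.7% of genes. The interaction, tested on 6 libraries per line, was −2.87 for Has2 (SE 0.09, adjusted p = 1.35e-45), −1.99 for Csf1 (SE 0.04), 1.85 for Egr1 (SE 0.05, adjusted p = 6.41e-50) and 6.72 for the endothelial adhesion gene Pecam1 (SE 0.63). The test called 4988 interactions higher and 5349 lower, of which 1215 and 1801 were at least 2-fold. With TMM 48.3% of the called genes were higher, with total counts only 26.3% and with scaling to mitochondrially encoded genes 7.6%. The median log2 value of all genes moved from −0.009 to −0.252 and −0.687 with these, to 0.093 with upper-quartile normalization and to 0.095 without a filter. The 9 lists called higher or lower were those of the activator induction without the fibroblast matrix, with 76 of 81 ribosomal protein genes higher and 1 lower and 200 of 359 Zfp genes lower and 60 higher (203 lower over the list alone). The others showed 31 higher of 33 oxidative phosphorylation (32 over the list alone), 13 of 15 mitochondrially encoded, 16 higher and 3 lower unfolded protein response, 25 and 8 G2/M, 27 and 6 G1/S, 7 and 14 NF-kB target and 3 and 13 nuclear noncoding RNA genes. The 6 positive list medians turned negative with scaling to mitochondrially encoded genes, to −0.158 for ribosomal, −0.164 for oxidative phosphorylation, −0.068 for mitochondrially encoded, −0.311 for unfolded protein response, −0.378 for G2/M and −0.354 for G1/S genes. Most of the mitochondrially encoded list is the scaling set itself, so the small median of that list follows from the setting. None of the 9 held with an estimated correlation (adjusted p between 0.215 and 0.319), and the 20 lists not called had an adjusted p of 0.0935 or more.

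The repressor line's response differed from that of the control line at fewer genes. Adgrg1 had an interaction of 2.94 (SE 0.10, 6 libraries per line, adjusted p = 6.59e-39), Adgrf5 of 1.89 (SE 0.36) and Padi3 of 1.52 (SE 0.26), and the collagen-binding proteoglycan gene Fmod was lower (−0.96, SE 0.10, adjusted p = 2.66e-11). The test called 193 interactions higher and 249 lower, of which 19 and 11 were at least 2-fold, and with scaling to mitochondrially encoded genes 61.8% of the called genes were higher against 43.7% with TMM. Integrated stress response genes were lower in 15 of 23 (18 over the list alone, median −0.281, adjusted p = 1.21e-23), among them Asns (−0.38), Trib3 (−0.61) and Sesn2 (−0.46). Of these 23 genes 10 were higher in the uninduced repressor than in the uninduced control line, a difference that the interaction does not remove. Matrix genes were lower in 13 of 26 (16 over the list alone, median −0.146, adjusted p = 4.58e-11), and G2/M genes higher in 11 of 36 (18 over the list alone, median 0.111, adjusted p = 6.82e-15). Heterochromatin and silencing factors were higher in 3 of 44 (4 over the list alone, adjusted p = 0.000498), Atf7ip (0.58) among them. These 4 lists held with an estimated correlation (adjusted p = 0.000531, 0.00663, 0.00243 and 0.00877). The G2/M median was 0.025 in the repressor and −0.091 in the control induction, and that of heterochromatin factors 0.011 and −0.037. By these medians both differences came more from a fall in the control line than from a rise in the repressor line. The number of members called depended on scaling. Scaled to mitochondrially encoded genes 7 stress response and 5 matrix genes were lower and 2 G2/M genes and 2 heterochromatin factors higher, and with total counts only 14 and 7 lower and 9 and 3 higher, with the list medians in the same direction.

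Other calls in that interaction were lost with an estimated correlation. Immediate early genes were higher in 5 of 27 (9 over the list alone, Egr1 with 0.31, adjusted p = 3.17e-05 and 0.0956 with an estimated correlation). The p53 targets were lower in 4 of 25 (5 over the list alone, adjusted p = 0.0222 and 0.15 with an estimated correlation), a call lost without uninduced control library 3 (0.153), uninduced repressor library 2 (0.0569) or induced repressor library 1 (0.0647). Ribosomal protein genes were lower in 2 of 81 (adjusted p = 0.000298, 0.742 with an estimated correlation and 0.141 without induced repressor library 1). Oxidative phosphorylation genes were lower in 1 of 33 (adjusted p = 0.00914, 0.57 with an estimated correlation, 0.113 without induced control library 2 and 0.104 without induced repressor library 1). The 21 lists not called had an adjusted p of 0.112 or more.

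Before induction the activator line had lower levels of cholesterol synthesis genes than the control line. Hmgcs1 (ENSMUSG00000093930.1, chromosome 13, 119690379 to 119708260), an early enzyme of sterol synthesis, was lower at 126 ± 2.8 against 210 ± 4.86 CPM (n = 3 per group, log2 fold change −0.73, SE 0.04, adjusted p = 1.5e-22), as was Msmo1 (−0.69). The matrix glycoprotein gene Thbs1 was lower at 945 ± 15.8 against 1540 ± 36.6 CPM (−0.70, adjusted p = 1.32e-34). The guanylate-binding protein gene Gbp7, for which DESeq2 gave no adjusted p, was lower at 0.323 against 2.97 CPM, and the protease inhibitor gene Timp1 was higher at 55.4 against 34.6 CPM (0.69). Among satellite models Gm26870 had 186 against 2 counts (ratio 83.3, 95% interval 22.7 to 693, adjusted p = 0.00821) and Gm10800 was at 18.9 ± 1.36 against 4.53 ± 0.916 CPM. The test called 1447 genes higher and 1710 lower, 45 and 47 of them at 2-fold, with 33.4% of genes without overlap against 10% by chance. With scaling to mitochondrially encoded genes 8.2% of the called genes were higher against 45.8% with TMM, and without uninduced control library 1 the genes higher numbered 929. Of 23 cholesterol synthesis genes 22 were lower and none higher (median −0.467, camera adjusted p = 1.88e-28), the only list to hold with an estimated correlation (0.0197).

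Other list calls between these uninduced lines were weaker. Ribosomal protein genes were higher in 34 of 81 (40 over the list alone, Rpl10a with 0.19, adjusted p = 3.29e-10), with a median that went to 0, 2 higher and 1 lower, and a call of Rpl10a that was lost (adjusted p = 0.166) with scaling to mitochondrially encoded genes. Oxidative phosphorylation genes were higher in 9 of 33 (11 over the list alone, adjusted p = 0.0112) and histone genes in 5 of 64 (4 over the list alone, adjusted p = 0.026), and their medians turned to −0.043 and −0.042 with that scaling. Glycolysis and hypoxia genes were lower in 9 and higher in 1 of 28 (11 lower over the list alone, Egln1 with −0.23, adjusted p = 0.0186). With an estimated correlation the adjusted p was 0.804 for histone genes and 0.647 for the other 3. Without uninduced activator library 2, 3 lists were called instead of 5 (adjusted p = 0.0544 for oxidative phosphorylation and 0.572 for histone genes), without library 3 glycolysis reached 0.0541, and without uninduced control library 1 histone genes reached 0.294. The 24 lists not called had an adjusted p of 0.0912 or more.

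Before induction the repressor line lay close to the control line. Sytl2 was higher at 7.69 against 2.37 CPM (n = 3 per group, log2 fold change 1.72, SE 0.14, adjusted p = 2.18e-15), and the sphingosine phosphatase gene Sgpp2 was higher (1.62, SE 0.28). Gbp7 was lower at 0.353 against 2.97 CPM (−3.04, SE 0.29) and the dynamin gene Dnm3 was lower (−1.60, SE 0.32). DESeq2 gave no adjusted p for Sgpp2, Gbp7 and Dnm3, so these calls were not made there. The test called 140 genes higher and 113 lower, 15 and 10 of them at 2-fold, with 18.4% of genes without overlap against 10% by chance. These counts fell without single libraries, to 79 and 58 higher without uninduced control library 1 or 2, and 83 and 69 higher without uninduced repressor library 2 or 3. Genes lower numbered 67 and 45 without uninduced control library 1 or 2, and 70, 64 and 48 without uninduced repressor library 1, 2 or 3. Integrated stress response genes were higher in 10 of 23 (15 over the list alone, median 0.112, adjusted p = 7.78e-15), Trib3 (0.34), Sesn2 (0.30) and the folate enzyme gene Mthfd2 (0.19) among them, and this list alone held with an estimated correlation (0.00467). With scaling to mitochondrially encoded genes 4 members were higher, and Mthfd2 lost its call (adjusted p = 0.136).

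The other calls between these uninduced lines did not hold with an estimated correlation. Histone genes were higher in 1 of 64 (adjusted p = 1.78e-07) and cholesterol synthesis genes in 2 of 23 (13 over the list alone, adjusted p = 1.14e-07). Matrix genes were higher in 6 and lower in 1 of 26 (10 and 2 over the list alone, Col1a2 with 0.13 and Pdgfra with 0.22, adjusted p = 0.00222). G2/M genes were lower in 1 of 36 (adjusted p = 0.002). Neural markers had no member called by edgeR over all genes (1 higher over the list alone, adjusted p = 0.0429, 0.115 without uninduced control library 2 and 0.144 without uninduced repressor library 3). With scaling to mitochondrially encoded genes 1 matrix gene was higher, and Col1a2 and Pdgfra lost their calls (adjusted p = 0.494 and 0.0646), and Pdgfra also with total counts only (0.0616). With an estimated correlation the adjusted p was 0.44 for histone genes, 0.377 for neural markers and 0.194 for the others. The 23 lists not called had an adjusted p of 0.0983 or more.

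The inductions of the repressor and control lines shared more genes than independent responses would. Of the called genes 20 rose and 16 fell in both, against 2.1 and 1.6 for independent responses (Fisher exact p = 1.67e-15 and 3.41e-13), and 2 were opposite, with Ccn1 rising and Hist2h4 falling in both. The shared genes fell in number without single libraries, to 7, 7, 7 and 11 higher without uninduced control library 1 or 3 or induced control library 2 or 3, and to 10 lower without uninduced control library 3. The activator and repressor inductions shared 406 genes lower against 276.9 (Fisher exact p = 1.08e-22) and 338 higher against 322.6 (Fisher exact p = 0.26). Another 586 moved in opposite directions. Without induced repressor library 2 the shared genes numbered 261 lower and 219 higher. The activator and control inductions shared 24 genes higher against 15.7 (Fisher exact p = 0.00943) and 17 lower against 12.6 (Fisher exact p = 0.154), with 29 opposite. That pair's genes higher numbered 9, 11 and 8 without uninduced control library 1, 2 or 3, 9 and 8 without induced control library 2 or 3, and 46 without induced activator library 3. Its genes lower numbered 9, 10 and 11 without uninduced control library 1, 2 or 3. They numbered 11 and 9 without induced control library 2 or 3, and 27 and 35 without induced activator library 1 or 3. The log2 fold changes correlated weakly (Pearson r = 0.054 and Spearman rho = 0.15 for repressor and control, and 0.096 and 0.129 for activator and repressor). For activator and control the sign depended on the measure (−0.033 and 0.077), and no p is given because genes are not independent. The Fisher tests above treat genes as independent, so their p-values are too small by an unknown amount.

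Among endogenous genes related to transgene parts, the NF-kB subunit gene Rela was lower in the activator induction (−0.13, adjusted p = 0.004), a call lost with RLE (0.0564), upper-quartile normalization (0.606) and DESeq2 (0.105) and without induced activator library 2 (0.0984). Among lists with too few tested members, Usp17la was the only 2-cell-stage gene tested of 27 and Krt14 the only epithelial marker of 14, and Usp17la was called in the activator and repressor inductions and Krt14 in none.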

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

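The tests of genomic DNA, of the library scaling, of RNA from other cell types and of neighbouring genes were chosen only after the result was seen, and the other tests after the data and the patterns had been seen but before their own outcome was. The results below call for a closer look because the change on induction differed between lines, by the interaction test. That test cannot separate the effector from the hours of induction in the activator line or from the doxycycline dose in the repressor line. Between the activator and the control line 4988 genes were higher and 5349 lower. The log2 values were 8.70 for the satellite sum, −2.87 for Has2, −1.99 for Csf1, −2.23 for Tnfaip3, 1.85 for Egr1, −2.00 for Dusp6, −1.96 for Plk2, −0.86 for Setdb1, −1.48 for Zfp462, −1.33 for Gas5 and 6.72 for Pecam1. Smaller values were 0.48 for Pdia3, 0.77 for mt-Co1, 0.63 for Atp5b, 0.66 for the spindle gene Hmmr, 0.73 for Mcm4, 0.57 for Rplp0 and −0.19 for Rela, which was lost with upper-quartile normalization (adjusted p = 0.153). Of these Pdia3, Atp5b, Hmmr and Rplp0 turned negative with scaling to mitochondrially encoded genes, and the calls of mt-Co1 (0.09, adjusted p = 0.236) and Mcm4 (0.05, adjusted p = 0.529) were lost. List medians were −0.70 for NF-kB targets, −0.38 for Zfp genes and −0.50 for nuclear noncoding RNAs, and, turning negative with that scaling, 0.37 for unfolded protein response, 0.61 for mitochondrially encoded, 0.51 for oxidative phosphorylation, 0.30 for G2/M, 0.32 for G1/S and 0.52 for ribosomal protein genes. None of these 9 list calls held with an estimated correlation (adjusted p between 0.215 and 0.319). Since mt-Co1 and most of the mitochondrially encoded list belong to the scaling set, their change under scaling to mitochondrially encoded genes follows from the setting.

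Between the repressor and the control line 193 genes were higher and 249 lower, for the same reason of a difference between lines. The log2 values were 2.94 for Adgrg1, 1.89 for Adgrf5, 1.52 for Padi3, 0.62 for Ccn2, 0.80 for Ankrd1, 0.58 for Atf7ip, 0.38 for Mbd1, 0.31 for Egr1, 0.21 for the cytokinesis gene Anln and 0.20 for the proliferation marker Mki67. The calls of Anln and Mki67 were lost with scaling to mitochondrially encoded genes (adjusted p = 0.0522 and 0.0614). The log2 values were −0.96 for Fmod, −0.61 for Trib3, −0.46 for Sesn2, −0.46 for Lox, −0.39 for Rpl7l1, −0.38 for Asns and −0.36 for Col1a2. The value of Rpl7l1 came from its rise in the control line, as the repressor libraries, uninduced and induced, held 121.3 to 127.5 CPM. The lists that held with an estimated correlation had medians of −0.28 for integrated stress response, −0.15 for matrix, 0.11 for G2/M and 0.06 for heterochromatin genes. Those lost with it had medians of 0.14 for immediate early genes (adjusted p = 0.0956) and −0.05 each for p53 target (0.15), oxidative phosphorylation (0.57) and ribosomal protein genes (0.742). For G2/M and heterochromatin genes the control induction had medians of −0.091 and −0.037, and the repressor induction 0.025 and 0.011. Their interaction values thus came more from the control line. Of 23 integrated stress response genes 10 were already higher in the uninduced repressor than in the uninduced control line.

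The rise of the satellite-bearing models in the activator line was set against carried-over genomic DNA and against library scaling, both tests being chosen after the result was seen. The satellite fold was 12.7 times the fold of 1572 olfactory and vomeronasal receptor genes, 128 against 10.1. DNA would give both the same fold only if the uninduced receptor counts were DNA too, spread over the genes by length. The receptor genes with a count in the uninduced libraries numbered at most 0.372 times those of such a draw, so this ratio does not decide on DNA, which stays open here. Over 6 other scalings the log2 change of the sum stayed between 6.26 and 7.11, so scaling did not produce it. Transcription of the targeted repeat may be the source of the rise, and carried-over DNA is not excluded as part of it. It also stays open which satellite copies were transcribed, as reads of near-identical copies cannot be assigned, and how much of the rise came from elsewhere in the arrays, which the table does not count.

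The rise of silent genes in the activator line was tested against 4 explanations, of which only the search for satellite words was chosen before its own outcome was seen. Against genomic DNA, receptor genes with a count in the induced libraries numbered at most 0.166 times those of a length-proportional draw, and against misplaced satellite reads, 1.1% of the 819 genes held a 15-base word of the repeat. Against RNA of another cell type, at most 23.1% of the silent members of any of 7 marker lists rose 8-fold, the highest being muscle with Actc1, Myh3 and Ttn. The 7 lists hold no markers of liver, kidney or germ cells, so RNA of such cells was not tested in this way. Neighbours were in the direction that activation along the chromosome predicts, since 33.2% of the rising genes had another within 100 kb against a mean of 16.2% in 1000 random sets of silent genes that passed the filter, a ratio of 2.06. Spread of activation along the chromosome is thus a candidate explanation for part of the pattern, but overlapping gene models and an unstated strand setting could also place reads on neighbours, and off-target binding of the activator was not tested. The random sets were not matched for transcript class or gene family. Genes in the first assembled 10 Mb of a chromosome were not called as a list (camera adjusted p = 0.545). Of these 491 of 1170 were higher, against 6190 of all 16216 genes.

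The fall of intronic transcripts beside the rise of ribosomal protein genes in the activator line was tested with measures chosen after this pattern had been seen, among them the scaling without Gm26917 and Gm42418, but before their own outcome was. Matched on transcript length the 159 intronic transcripts stayed below protein-coding genes by a median log2 difference of −1.34 (95% interval −1.54 to −1.23), and matched on GC content by −1.25 (−1.42 to −1.11). Both intervals come from 1000 bootstrap draws over the transcripts and measure the spread between transcripts, not between libraries. Without Gm26917 and Gm42418 in the scaling the difference between ribosomal protein genes and intronic transcripts was 1.70 as before, but a scaling moves all genes alike, so this comparison could not decide on their part, which stays open. A lower share of unspliced or short-lived RNA after 6 h may be the source, as may a difference in RNA fractions recovered, and the data here hold no measure of synthesis or decay to separate them.

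The groups were also compared with other splits of the same libraries, tests chosen after the calls of the real groups had been seen but before their own outcome was. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and only 1 of them, the real one, called as many genes in each comparison. The real split called 12218 genes in the activator induction with 0 as the highest of the others, 1590 with 0 in the repressor induction and 75 with 3 in the control induction. It called 3157 with 1 for the uninduced activator line and 253 with 1 for the uninduced repressor line. For the activator and control interaction 3 of 100 splits called as many as the real 10337, the highest other being 11032. The 2 others kept the induced libraries of each line together, and splits that mixed them called at most 13. The share of 3 in 100 therefore follows from how many such splits were drawn, and is not taken here as excluding chance. For the repressor and control interaction 6 of 100 splits called as many as the real 442, the highest other being 1621, a share that does not exclude chance and does not measure it either. The 5 others kept the induced libraries of each line together and so exchange differences between lines for differences of induction, which points to the structure of the lines, and splits that mixed induced libraries called at most 30. List calls by camera set the real groups apart less than gene calls did. The real split called 10 lists in the activator, 10 in the repressor and 8 in the control induction, and the highest of the others 9, 5 and 8. For the uninduced activator and repressor lines it called 5 and 6 lists, with 6 and 5 as the highest others, and 4 of the 10 splits called as many as the real 5. In the interactions 25 and 15 of 100 splits called as many lists as the real 9 and 8, the highest other being 12 in both. Splits that exchange part of the libraries keep part of a real difference, so these are not counts under no difference, but they leave the number of list calls short of evidence for the groups.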

How the results depend on the processing

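Of the alternatives, total counts only, scaling to mitochondrially encoded genes and TMM without Gm26917 and Gm42418 were chosen after seeing the data, and the cause of the differences below was not tested unless the setting itself forces them. A minimum of 1 on the log2 scale necessarily lowered the calls, to 1554 higher and 1928 lower in the activator, 50 and 23 in the repressor and 0 and 2 in the control induction. It gave 1215 and 1801 in the activator and 19 and 11 in the repressor interaction, and 45 and 47 for the uninduced activator and 15 and 10 for the uninduced repressor line. An adjusted p of 0.01 likewise gave 517 and 423 in the repressor and 13 and 17 in the control induction, 97 and 155 in the repressor interaction, 833 higher for the uninduced activator line and 57 and 46 for the uninduced repressor line. Shared genes at that threshold numbered 181 higher and 229 lower for activator and repressor, 9 and 6 for activator and control, and 6 and 9 for repressor and control.

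With total counts only, genes higher numbered 3955 in the activator induction, 76 in the control induction, 2686 in the activator interaction and 79 for the uninduced repressor line, and genes lower 407 in the repressor and 21 in the control induction. Scaled to mitochondrially encoded genes, the counts were 1405 higher and 12966 lower in the activator induction, 348 and 353 in the repressor induction, and 3 higher in the control induction. They were 970 and 11857 in the activator interaction, 102 and 63 in the repressor interaction, 267 and 2995 for the uninduced activator line and 38 and 41 for the uninduced repressor line. That scaling sets to 0 the change of genes that rose in the activator line, so genes that rose less than these turned negative. Examples in the activator induction were Ccng1 (−0.22), Pdia3 (−0.18), Calr (−0.23), Atp5b (−0.14), Ccnb2 (−0.05), Mcm4 (−0.08), Mcm7 (−0.14), Rplp0 (−0.15), Rpsa (−0.16) and Sparc (−0.28). Examples in the activator interaction were Pdia3 (−0.20), Atp5b (−0.06), Hmmr (−0.02) and Rplp0 (−0.11).

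DESeq2 called 25 genes higher in the control induction, 117 higher in the repressor interaction and 62 higher and 63 lower for the uninduced repressor line. A fit of the compared groups alone called 269 and 244 for the uninduced repressor line. The control fall of the satellite sum passed the threshold with DESeq2 (−1.68, adjusted p = 8.05e-13), with scaling to mitochondrially encoded genes (−1.76, 8.44e-25) and in a fit of its groups alone (−1.69, 3.72e-10). The repressor interaction of the sum passed with the same settings (−1.17 with 0.0331, −1.09 with 0.0117 and −1.14 with 0.00457), while the repressor fall was lost with limma-voom (−2.80, 0.285). These p-values rest on 46 to 428 counts per group and changed with the tool, the scaling and the groups fitted, for a reason not tested here. A replicate block across lines gave 53 genes lower in the control induction and a control satellite change of −1.66 (adjusted p = 0.0319). The replicate numbers do not pair libraries, since 9 pair correlations lay between −0.023 and 0.025 and in 4 of 9 cases the best match carried the same number.

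With an estimated correlation, camera called 0 lists in the activator induction, 3 in the repressor induction, 0 in the activator and 4 in the repressor interaction, and 1 each for the uninduced activator and repressor lines. Fry, which tests a list against no change, called 25 in the activator induction, 27 in the activator interaction and 9 for the uninduced activator line.

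With single libraries left out, genes higher ranged from 12 to 28 and lower from 20 to 30 in the control induction, and genes lower from 484 to 607 in the repressor induction. For the uninduced lines genes higher ranged from 929 to 1295 for the activator, and from 58 to 110 with 45 to 81 lower for the repressor. Shared genes ranged from 219 to 391 higher and 261 to 448 lower for activator and repressor, 8 to 46 and 9 to 35 for activator and control, and 7 to 17 and 10 to 17 for repressor and control. Lists called for the uninduced activator line ranged from 3 to 6.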

Other observations

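Transcript classes moved apart in the activator line within 6 h of induction. Of 159 sense intronic transcripts 117 fell and 9 rose (median log2 fold change −1.147), and small nuclear, nucleolar and micro RNA genes fell as well, with 48 of 96, 99 of 171 and 62 of 119 lower and 3, 10 and 18 higher. Of 840 unconfirmed transcripts 521 fell and 133 rose (median −0.88). Processed pseudogenes, copies of spliced messages, rose in 425 and fell in 107 of 1059, with a median of 0.372 that turned to −0.366 with scaling to mitochondrially encoded genes, while the 5 falling classes kept their direction under each of the scalings. In the repressor induction 4 intronic transcripts fell and none was called higher by edgeR, and 28 unconfirmed transcripts fell and 2 rose. The share of counts held by Gm26917 went from 11.41% to 17.06% in the activator line, while the TMM factor went from a mean of 1.025 to 0.878.

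Genes of the germline and of other cell types were among those that became expressed in the activator line. The germline genes Piwil2, which protects germ cells from transposons, and Syce1, a synaptonemal complex protein, reached 4.25 and 2.55 CPM, from 7 and 0 counts (Syce1 at least 56.1-fold higher, adjusted p = 5.62e-20), with 5 higher and none lower among the 8 of 39 germline genes that were tested. A silent gene passes the filter only when enough libraries hold counts, which a rise provides, so this count and those of the marker lists below describe the tested members only. Pecam1 (chromosome 11, 106654217 to 106750628) went from 0.274 ± 0.0951 to 21.3 ± 2.67 CPM (log2 fold change 6.19, SE 0.18), the only 1 of 13 endothelial markers under 1 CPM before induction to rise 8-fold, and 4 rose and 1 fell among the 5 of 15 that were tested. The astrocyte filament gene Gfap reached 6.59 ± 0.932 CPM, although 3 of the 5 neural markers tested, of 17, fell and the list median was −0.653 against a mean of 0.887. Among the 8 of 18 macrophage markers tested 4 rose and 1 fell, with Itgam at least 18.1-fold higher and Lyz2 at a ratio of 129 (95% interval 22.7 to 5150). Among the 8 of 17 adipocyte and chondrocyte markers tested 4 rose and 2 fell, with Adipoq at least 50.6-fold higher and the osteoblast factor gene Runx2 lower at 31.5 against 106 CPM. Of the 8 of 16 muscle markers tested 5 rose and 1 fell, Ttn with a log2 fold change of 4.23 and Actc1 and Myh3 at ratios of 132 (23.1 to 5250) and 102 (17.9 to 4100), and the 4 of 15 pluripotency genes tested divided into 1 higher and 1 lower.

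The newly expressed genes stayed at low levels and lay on every chromosome. Of the 819 genes that lay under 1 CPM and rose 8-fold, 812 were not satellite-bearing models, and the median of these went from 0.046 to 1.85 CPM with a highest value of 37 CPM. Under 1 CPM before induction lay 34931 genes of the table, of which 3210 passed the filter, so most silent genes had too few counts to be tested. Of the 812 rising genes 804 lay on assembled chromosomes, between 16 and 78 per autosome, with 30 on the X chromosome and 1 on the Y chromosome. Of the 812 genes, 3 were also higher in the uninduced activator line, none was called by edgeR in the control induction (75 genes called in all), and 545 were higher in the interaction. The 812 were picked for low levels in the uninduced activator libraries and for their rise over them. The counts of 3 and 545 therefore follow in part from that choice and do not measure expression before induction.

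Mitochondrial RNA followed the same induction. The mitochondrial chromosome held 0.92% to 0.974% of the counts in the induced activator libraries, against 0.641% to 0.676% in the uninduced ones. The choice of scaling rests on whether these transcripts are taken as constant, since scaling to them moved the calls higher in the activator induction from 6190 to 1405.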
